A study of soil metagenome with 12 samples.

How the data were processed

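Total DNA and total RNA of 6 soil, sludge or sediment samples were measured on single-colour Agilent arrays, 1 array per sample and molecule. Per the labels' protocols, DNA was cut with restriction enzymes and labelled with Cy3 by random priming. RNA was tailed with poly(A), reverse transcribed from an oligo-dT primer and labelled with Cy3 during in vitro transcription. Grouping came from the sample titles, which number the 5 contaminated sites and mark the control.

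Per the file headers, the authors extracted spot values with Agilent Feature Extraction 10.5.1.1 under its protocol for single-colour gene expression arrays, also for the DNA arrays. The deposited scanner files give spot intensity on a linear scale as a processed signal, a median signal and a local background, with flags for outliers, saturation and signal well above background. The authors' deposited value table holds log2 values. Each of its columns equalled log2 of the processed signal minus the median of that array, within 0.001, so its direction and scale are known, and its column medians are 0 apart from rounding.

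The 536 control spots were left out of all fits and outlier spots were set to missing. The main values were log2 of the processed signal minus the 75th percentile of each array. Under 50% of probes were detected in every fit (41.3% for DNA, 10.8% for RNA, 23.0% for RNA against DNA at the contaminated sites, 26.0% over all arrays), so the percentile was taken over the probes detected on all arrays of the fit, 327, 803, 123 and 123 probes. A probe was tested when it was well above background on at least 1 array of the fit. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) and p-values adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The lone control array was assumed to vary like the contaminated sites. Figures were drawn with matplotlib 3.10.9. Where a probe was not above background on any array of a group, the difference is given as a bound against the higher of its own value and the lowest signal well above background, per array, as means of scaled log2 values. Such a bound holds for the processed signal under the main scaling, and other background corrections or scalings can fall below it.

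The tests and alternatives were fixed before the data were examined, apart from those named in the closing section as chosen later. The alternatives covered scaling, background correction, filters on dim probes, an intensity trend, averaging of the probes of a target, the authors' value table, slide and site terms, and leaving out each site. Slides and scans coincided. Slide 1 held the DNA arrays of sites 1, 3 and 4 and of the control soil, slide 2 those of sites 2 and 5, and slide 3 all RNA arrays. Per the labels, the same number marks the same place in both molecules, so RNA and DNA of a site are paired. Same-site deviations from the group means correlated at r between −0.032 and 0.088 across probes, and 1 of the 5 RNA arrays correlated best with the DNA of its own site.

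The rule for named probes took, per comparison, the largest differences in each direction with all 5 sites on the same side (at least 4 of 5 pairs for RNA against DNA), 1 probe per target, well above background on every array of the brighter group, first among probes past the threshold and otherwise below it. Since the files do not pair identifiers with gene names, at most 2 identifiers per direction are printed for a comparison. The planned 12 per direction, and 3 per site for single sites, were reduced to this. The 34 gene lists planned by keyword were matched against the probe and target identifiers, and 0 probes matched, so no list was tested.

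Each fit was tested on simulated data drawn from the means and spreads of the real probes, with 200 changed probes of known size. A first mix held changes of 2-, 4- and 16-fold, and a second mix with 256-fold added was run after the first had been seen. At 16-fold, 0 of 66 changed probes in the first mix and 1 of 50 in the second were called for DNA against the control soil, over 10466 probes. For RNA against the control soil, over 3651 probes, it was 2 of 66 and 18 of 50, for RNA against DNA at the contaminated sites, over 10200 probes, 36 of 66 and 30 of 50, and for the fourth comparison, over 10706 probes, 0 of 66 and 1 of 50. At 256-fold, 24, 37, 50 and 9 of 50 were called, in the same order. The share recovered thus varied with the mix that was simulated. Unchanged probes were called at most 5 times in a fit, for RNA against the control soil in the second mix. Noise was drawn independently for each probe and array, with no background floor or slide shift. For RNA against DNA the unchanged probes had no difference, unlike most real probes. Recovery in the real data can therefore differ. The number of arrays limits the precision.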

Results

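Community DNA and RNA from 5 contaminated sites and 1 control soil were hybridised to a custom microbial array that carries probes for biodegradation genes and for 16S ribosomal RNA genes, per the labels. Site 1 was canal soil and sludge at Vatwa, site 2 secondary sludge from the reactor of a treatment plant at Vatwa, site 3 river sludge at Vapi, site 4 sludge from the effluent stream of the Vapi treatment plant, and site 5 river sediment at Nandesari. The control soil came from a place without known chemical contamination. Each of the 6 samples gave 1 DNA array and 1 RNA array, so the 12 arrays hold 5 contaminated samples and 1 control for each molecule. The sites are separate places and no site was measured again with the same molecule, so every SD and p-value given here rests on the spread between sites. In the limma fits other than RNA against the control soil, this spread was pooled over all probes into 1 common value and treated as known. The SE and p-value of a probe in those fits therefore do not follow its own spread between sites. In the RNA fit that averaged the probes of a target, the SE and p-value of a target followed its spread only in part. The array held 15207 probes for 930 targets, with 4 to 160 probes per target. The files give each target only as an identifier and do not pair it with a gene name, so probes were grouped by their place in the probe numbering. The number of arrays limits the precision of all values.

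On the DNA arrays, 9134 probes were well above background at site 1, 490 at site 2, 7010 at site 3, 9085 at site 4 and 2138 at site 5, against 9817 in the control soil. On the RNA arrays the counts were 1715, 1203, 1107, 1153 and 1923 at sites 1 to 5 and 2758 in the control soil. The mean was 5571 ± 4022 probes for DNA and 1420 ± 373 for RNA at the contaminated sites (SD, n = 5 each). RNA was lower at 4 of the 5 sites, with a mean difference of −4151 probes. That difference did not pass an exact two-sided sign-flip test over the 5 pairs (p = 0.1875, where 0.0625 is the smallest p that 5 pairs allow). The DNA arrays of sites 2 and 5, which had the fewest detected probes, lay on a slide of their own. Without these sites the mean difference was −7085 probes over the other 3 pairs (exact two-sided sign-flip test, p = 0.25, the smallest p that 3 pairs allow).

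Detection of RNA was concentrated in a group of probes called the run here. It is a stretch of consecutive probe numbers in which the target identifiers start a new alphabetical order, together with a later set of probes for the same targets. It holds 880 probes for 110 targets with 8 probes each, which leaves 14327 probes for 820 targets outside it. The run, and the tests that use it, were chosen after the values were seen. On the RNA arrays of the contaminated sites, 772 ± 11.02 of the run probes were detected (SD, n = 5), and 786 in the control soil. Outside the run 648 ± 362 probes were detected at the contaminated sites (SD, n = 5) and 1972 in the control soil. On the DNA arrays of the contaminated sites, 458 ± 235 run probes and 5113 ± 3839 other probes were detected (SD, n = 5). Of the 110 targets of the run, 93 had at least 50% of their probes detected on every RNA array and 5 on none. Of the 820 other targets, 6 were detected on every RNA array by the same measure and 734 on none.

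**Figure D1:**
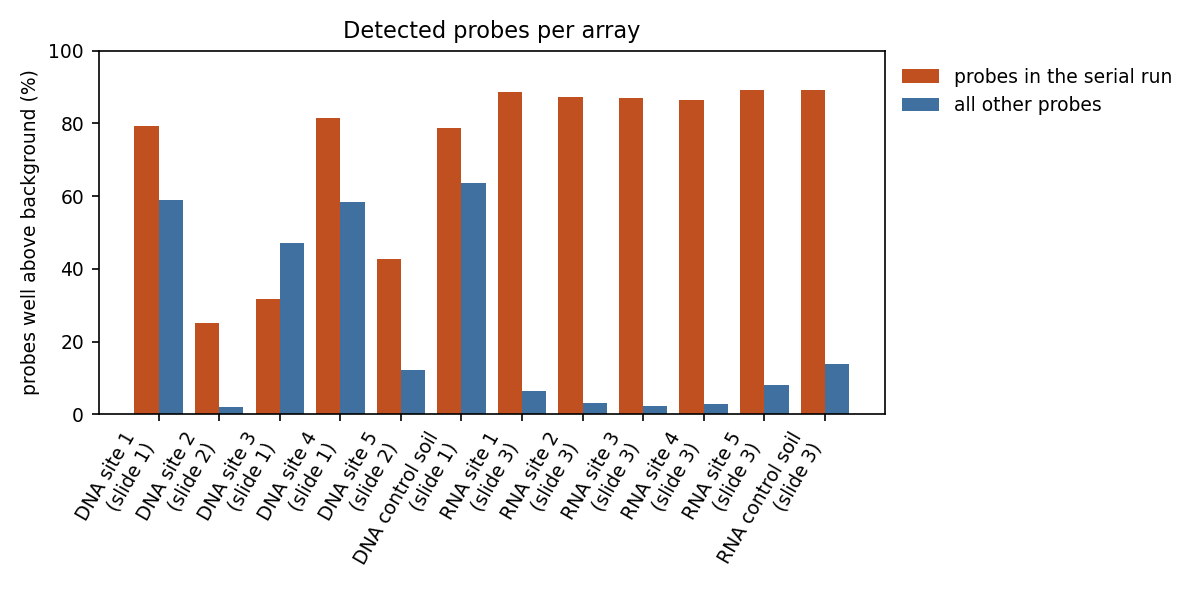
Percent of probes well above background on each of the 12 arrays (vertical axis, linear from 0), for the 880 probes of the run (orange bars) and the 14327 other probes (blue bars). Each bar is 1 array and has no error bar. On the RNA arrays 86.4% to 89.3% of the run probes were detected, against 2.39% to 13.8% of the others.

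Within each sample, the median log2 signal of the run stood further above that of the other probes in RNA than in DNA. The difference between RNA and DNA in this gap was 10.45 ± 1.49 log2 units over the 5 contaminated sites (SD, n = 5), with the same sign at all 5 sites. With the control soil as a sixth pair it was 10.37 ± 1.35 (SD, n = 6). No p-value is given, since the run was chosen after its probes were seen. Under 50% of the other probes were well above background on the RNA arrays and on the DNA arrays of sites 2, 3 and 5, so the size of the gap depends on how background was treated. With normexp background correction it was 6.68 over the 5 sites. Up to 204 probes of the run were saturated on an RNA array of a contaminated site, at site 1. In every fit with RNA arrays the scale rested mostly on run probes. The scale of the site 1 RNA array may therefore itself rest on saturated values.

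The first comparison asked how the gene content of the contaminated communities, as DNA, differed from that of the control soil. Most probes detected on the DNA array of a contaminated site were also detected on that of the control soil. On the control soil array 63.7% of probes outside the run were detected, and so were 88.5% of the ETG spots and 58.5% of the E1A spots, which the files mark as controls. The shared part was 97.1% of the probes detected at site 1, 94.1% at site 2, 98.4% at site 3, 94.8% at site 4 and 98.97% at site 5. At all 5 sites 327 probes were detected, a count capped by the 490 detected at site 2, and none of them was missing in the control soil. Another 549 probes were detected only in the control soil and 726 at 1 or more sites but not in the control soil. None of 10518 tested probes passed the threshold (limma, Benjamini-Hochberg adjusted p under 0.05), and 138 had an unadjusted p under 0.05. Chance alone would give about 525.9 such probes, so the 138 are no excess. The 767 tested probes of the run gave no call, and neither did the 9751 others.

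Among probes with all 5 sites on the same side of the control and well above background on each array of the brighter group, the largest DNA differences belonged to G_BA_110702 (target AY731710), at 5.71 ± 1.65 log2 units above the control (SE; 5 sites against 1 control), and G_BA_111355 (target AB066362), at 4.60 ± 1.65 above it. The largest in the other direction were in the run, at −3.71 ± 1.65 for G_BA_105633 (target X86394) and −3.46 ± 1.65 for G_BA_111184 (target DQ452025). All 4 had an adjusted p of 0.99997 in limma and did not pass. The lower 2 were well above background at 2 of the 5 sites. Averages over the probes of the target were 1.77 for AY731710, 2.30 for AB066362, −0.60 for X86394 and −2.95 for DQ452025. With normexp background correction the lower 2 probes were at −1.11 and −0.90. The median difference over all tested probes was 0.42 log2 units and turned to −0.30 when arrays were scaled by their medians. It was 0.06 without site 3, 0.12 without site 2 and 1.42 with normexp, and at single sites it ran from −0.86 at site 4 to 1.79 at site 3. The count of calls was 0 with slide as a block (56 at an unadjusted p under 0.05) and 0 within the slide that holds the control array and sites 1, 3 and 4 (182 at an unadjusted p under 0.05). Both counts at an unadjusted p under 0.05 were also fewer than chance gives.

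The second comparison asked the same of the RNA. Tested probe by probe, 0 of 3769 probes passed the threshold (limma, adjusted p under 0.05), with 281 at an unadjusted p under 0.05 and a smallest adjusted p of 0.504. Chance alone would give about 188.45 probes at that unadjusted p. The run was detected to a like extent in all samples, since 7 of its probes were detected at all 5 sites and not in the control soil, and 6 only in the control soil. Outside the run, 981 probes were detected only in the control soil and 1034 at 1 or more sites but not there, of which 932 at a single site.

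By the same rule, the largest RNA differences with all 5 sites on the same side of the control were in the run, and none of the 4 probes named here passed. G_BA_111303 (target AB021377) was at 4.43 ± 2.13 log2 units (SE; 5 sites against 1 control; limma, adjusted p = 0.726) and was saturated at site 3, so its size there is not measured. G_BA_111002 (target AF375937) was at least 4.18-fold above the control (adjusted p = 0.637), where it was not well above background. G_BA_111155 (target DQ110881) was at −8.46 ± 1.92 (adjusted p = 0.504) and was well above background at 1 of the 5 sites. G_BA_105508 (target DQ295876) was at −7.68 ± 2.21 (adjusted p = 0.580), well above background at 2 of the 5 sites. With normexp background correction the 4 probes were, in this order, at 4.26, 1.41, −4.88 and −4.87 log2 units. The bound of 4.18-fold for G_BA_111002 thus holds only for the processed signal, and the sizes of the 2 lower probes are set largely against background.

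Of 18 alternatives, 13 also gave no call and 5 gave calls. When the probes of each target were averaged before the fit, 11 of 744 targets passed, 2 higher and 9 lower at the contaminated sites than in the control soil. All 11 were targets of the run, of which 106 were tested. They included AF375937, at least 3.77-fold higher, with 0 of 8 probes well above background in the control soil (limma, adjusted p = 0.00957, with 0.00494 to 0.9997 for G_BA_111002 over its alternatives). DQ110881 was at −4.30 ± 0.89 (SE; adjusted p = 0.00176, with 5.59e-13 to 0.852 for G_BA_111155 over its alternatives). DQ295876 was at −3.72 ± 0.87 (adjusted p = 0.00802, with 1.02e-10 to 0.9995 for G_BA_105508 over its alternatives). AB021377 did not pass, at 2.25 (adjusted p = 0.381, with 0.00331 to 0.9996 over the alternatives of G_BA_111303). In this averaged fit limma drew the spread of each target toward that shared by all tested targets. For DQ110881 the SD between sites was 1.89, yet the SE was 0.89. With 1 control array, an SE from its own spread alone would exceed that SD. The SE was below the SD for all 11 targets, so their SE and p-values understate the spread between sites.

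**Figure D2:**
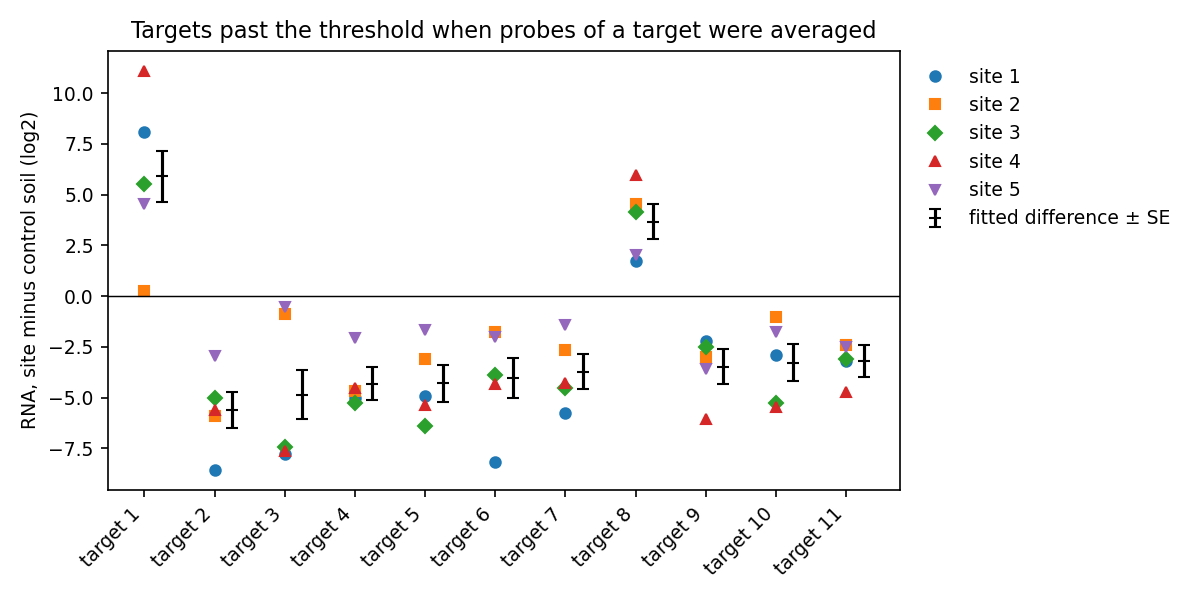
RNA difference from the control soil in log2 units (vertical axis) for the 11 targets past the threshold in the alternative that averaged the probes of a target. Without averaging, 0 probes passed. Symbols are the 5 sites and the black bars the fitted difference ± SE. The SE was drawn toward the spread of all tested targets and is below the SD between sites for each target shown. The 9 lower targets have all sites below 0. The 2 higher targets, at positions 1 and 8, had 1 and 0 of 8 probes well above background in the control soil, and the first had 0 of 8 at site 2. The lower targets at positions 3 and 7 were detected at 2 of the 5 sites, so the sizes of these 4 are set against background and their order is not measured.

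Without a filter on dim probes 71 probes passed, of which 58 were in the run, and with normexp background correction 31 passed, all in the run. The lowest adjusted p given above for G_BA_111002, G_BA_111155 and G_BA_105508 came from the fit without this filter. Their fitted differences were unchanged there, so these values do not reflect larger differences. Without site 5, 1 probe passed (G_BA_105495, lower, in the run), and 4 passed when all 12 arrays shared 1 fit. The median difference of all tested probes was −0.59 log2 units, made up of −0.08 in the run and −0.70 outside it, and the median outside the run was 0.28 with normexp. The E1A control spots, which the files mark as positive controls, were themselves brighter on the control array, at 10.98 log2 units against 9.06 ± 1.06 at the contaminated sites (SD, n = 5). When arrays were scaled by these spots the median outside the run became 0.72 and no probe passed. All RNA arrays lay on 1 slide, so no slide term applied.

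The third comparison set RNA against DNA at the 5 contaminated sites. Under the scaling used here, 220 of the 841 tested run probes were higher in RNA and 195 were lower, while all 9547 tested probes outside the run were lower. In total 9962 of 10388 probes passed (limma, adjusted p under 0.05), of which 220 or 2.21% were higher. The count of higher probes was 124 without site 1 and 145 without site 5. With normexp background correction 9840 probes passed and 0 of them were higher, and the median of the run was −0.14 log2 units. The scale rested on 123 probes detected on all 10 arrays, and 122 of these were in the run. On the RNA array of site 1, 204 run probes were saturated, so its scale may not be measured. These differences are therefore relative to the run. With arrays scaled by their medians, 2437 probes passed and 38.4% of them were higher, with quantile normalization 1459 and 46.5%, and with the 75th percentile of all probes 2274 and 53.9%. The median difference of the run moved from 0.68 log2 units under the scaling used here to 9.23 under median scaling, and that of the other probes from −8.86 to −0.37, so the median of the run stayed above that of the other probes while the direction of single probes depended on the scale.

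The named probes higher in RNA were both in the run. G_BA_105324 (target AF230641) was at least 8.80-fold higher relative to the run (limma, adjusted p = 1.49e-07), as it was not well above background on any of the 5 DNA arrays. RNA was above DNA in the 4 pairs that had a value. The average of the 8 probes of this target gave −0.27 log2 units instead (adjusted p = 0.777). G_BA_105586 (target EF530572) was at 3.71 ± 0.92 log2 units (SE; adjusted p = 6.24e-05). It was well above background on 2 of the 5 DNA arrays, so this size is set mostly against background. With normexp background correction these probes were at 1.13 and 0.96 log2 units and neither passed (limma, adjusted p = 0.234 and 0.283). The first of these sizes is below the bound of 8.80-fold, which holds only for the processed signal. Over all alternatives the adjusted p ran from 1.499e-10 to 0.777 for G_BA_105324 and from 1.05e-07 to 0.283 for G_BA_105586. The named probes lower in RNA lay outside the run. G_BA_108675 (target NT04RP1825) was at least 3563-fold lower and G_BA_108159 (target NT01REC0063) at least 3498-fold lower relative to the run (limma, adjusted p = 3.24e-47 for each). This p rests on a variance pooled over all probes and treated as known. The limma adjusted p was 4.85e-09 and 1.06e-08 without site 3, and 4.69e-05 and 0.000299 under median scaling. Both were detected on all 5 DNA arrays and not on the RNA arrays of these sites. The fitted differences of these 2 probes were −13.91 and −13.87 log2 units, and moved to −5.42 and −5.37 under median scaling and to −9.64 and −9.52 with normexp. Under median scaling the 2 higher probes, G_BA_105324 and G_BA_105586, were at 13.81 and 12.21. Molecule, labelling kit and slide changed together between these groups. With slide as a random block 10036 probes passed, but all RNA arrays lay on 1 slide and the estimated correlation within slides was −0.096, so this fit does not part slide from molecule.

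**Figure D3:**
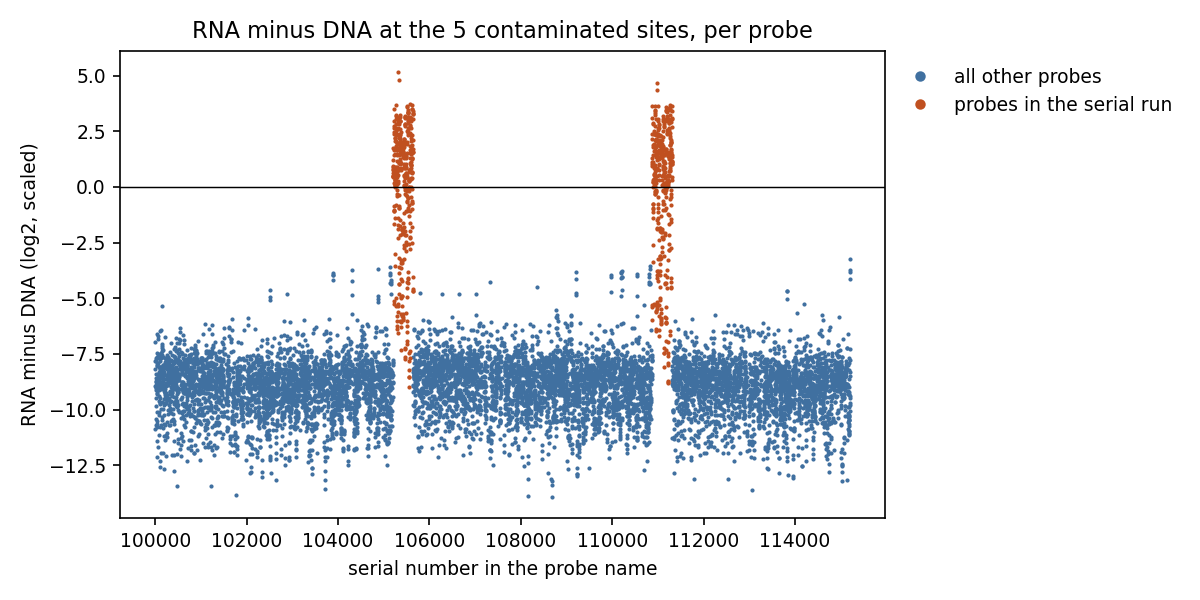
RNA minus DNA at the 5 contaminated sites for each of the 10388 tested probes, in log2 units after scaling (vertical axis), against the serial number in the probe name (horizontal axis). Each point is 1 probe, in orange for the run and in blue for the others. The run appears as a pair of narrow bands with a median of 0.68, and its lower values overlap those of the other probes, whose median was −8.86. Under median scaling these medians were 9.23 and −0.37.

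The fourth comparison asked whether RNA relative to DNA differed between the contaminated sites and the control soil. None of 10862 probes passed (limma, adjusted p under 0.05), and 139 had an unadjusted p under 0.05, where chance alone would give about 543.1. The median difference was −0.77 log2 units in the run and −1.18 outside it. Under median scaling it became 0.68 in the run and 0.26 outside it, so neither direction held across scalings. Over all tested probes it was −1.17, and −0.69 without site 2 and −0.56 without site 3. The 4 probes that the rule for named probes gave here were well above background on 2 of the 12 arrays (G_BA_102943), 5 (G_BA_114259), 3 (G_BA_111155) and 5 (G_BA_111097). Their differences rest on values at background, and none passed.

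The last comparison asked whether the RNA of a site resembled the DNA of the same site. After each probe was centred on its mean over the 5 sites, the mean Pearson r across 10388 probes was 0.020 for RNA and DNA of the same site and −0.0051 for different sites. Of the 120 ways to pair the arrays, 43 gave a mean at least as high (exact one-sided permutation test, p = 0.358). These are correlations across probes, which are not independent replicates. Of the 10388 probes, 9547 lay outside the run, where 2.39% to 7.94% of all probes were well above background on the RNA arrays of these sites. The correlations thus rest largely on values at background and could hardly show a match. Centring also ties the mean for different sites to that for the same site, so their contrast adds nothing. Within the 841 tested probes of the run the mean r of the same site was 0.075 (exact one-sided permutation test, p = 0.217). Across the 3345 probes tested in both molecules, the difference between contaminated sites and control soil in DNA correlated with that in RNA at r = 0.31, and at r = 0.46 over the 686 of them in the run. The sign was the same for 49.7% of all these probes and for 60.8% of those in the run. These shares depend on the scale: under median scaling the median difference of all tested probes went from 0.42 to −0.30 in DNA and from −0.59 to −0.23 in RNA. No value without a relation was computed for the shares or for r.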

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

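The tests in this part were chosen after the results were seen, except the regrouping of the 10 arrays. None of the 36 groups of 5 values that were examined was flagged for an outlying site, where chance gives about 1.8. With 5 values such a check has little power, so it does not show that the sites were alike. For example, 204 probes were saturated on the RNA array of site 1, against 3 to 86 at the other sites.

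Spots that the files mark as controls, which no comparison tested, lit up on the DNA arrays of slide 1: on these 4, 69.9% of the 78 ETG spots and 51.1% of the 200 E1A spots were well above background on average, against at most 1.30% of the negative control spots. Other control classes there were at 97.2% to 100% (DCP), 75% to 100% (eQC) and 0% (72 RC spots). On the DNA arrays of sites 2 and 5 the ETG share was 0% and 1.28%, and the E1A share 0% and 14.5%. On the RNA arrays the ETG share was 5.56 ± 6.86% (SD, n = 6). Spike-in material that ranks in DNA as it does on the RNA arrays is argued against, since the 10 E1A probes ranked differently from their order on the RNA arrays (Spearman rho −0.28 between mean levels), while they ranked alike among the RNA arrays (rho at least 0.988) and among the slide 1 DNA arrays (rho at least 0.964). Other added material, or the same material labelled by random priming, need not rank alike, so the ranks cannot decide on spike-in material of any kind. Binding without a matching target cannot be told apart from community DNA that holds the sequences of the ETG spots. On every slide 1 DNA array the ETG share was at least 1.06 times the share of probes outside the run, which either would give, and what these spots match is not given in the sources used here.

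Probes of the run were detected on RNA arrays where most other probes were not. Probes that are equally bright with any sample would give a like gap in both molecules, which the values argue against. The gap between run and other probes averaged 11.52 log2 units in RNA and 1.14 in DNA of the same samples. In DNA of the contaminated sites it ran from −0.77 to 2.66. The difference of 10.37 depends on background but was at least 6.68 in each alternative run over the 5 sites. The run was chosen after this pattern was seen, so these values describe the pattern and are no independent test. The labelling kit and slide of the RNA arrays cannot be told apart from the molecule, because 0 RNA arrays shared a slide with a DNA array. A biological hypothesis is that the run holds the ribosomal RNA probes of the array, which abundant ribosomal RNA would light up. The run held 99.27% to 99.67% of the probe signal on the RNA arrays and 4.01% to 29.83% on the DNA arrays. Abundant ribosomal RNA would give this, but the shares do not part it from labelling kit or slide. It was not decided here: 0 probes carry a 16S annotation in the files. The files pair no probe with a gene name, so this count says nothing either way.

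More probes outside the run were detected in the RNA of the control soil than at any contaminated site. The signal yield of the RNA array stays open, as its measures went different ways: the mean level of 96 E1A spots followed the number of detected probes outside the run over the 6 RNA arrays (Pearson r = 0.89, exact permutation p = 0.00139; Spearman rho = 1, exact permutation p = 0.00278; 1 relation computed). Without the 2 arrays farthest from the median level, the control soil and site 5, r was 0.64 over 4 arrays, so the relation rests in part on them. The bright corner spots went the other way, with a median log2 signal of 8.59 on the control soil RNA array against 10.299 to 12.22 on the others. The median run signal was 15815 in the control soil. It was higher at site 1 (33742) and site 5 (18247), and lower at site 2 (8854), site 3 (3828) and site 4 (4747). More kinds of transcripts in the control soil stay open: a first test, the median difference outside the run with arrays scaled by E1A spots, gave 0.72, which by its prediction counted against them. After that result was seen it was judged unsound, since scaling also lifts values at background, and was replaced by the share of contaminated-site values of these probes not above background, 78.4%, which decides nothing.

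The count of 9962 probes between RNA and DNA was compared with other splits of the same 10 arrays. Of 100 splits, 1, the real one, gave as many, and the highest other gave 9330. Fewer than 5 in 100 splits gave as many, the mark set beforehand, which argues against chance over splits that ignore the pairing of sites. The sites are paired, and splits that keep the pairing cannot decide it, as given below. Of the other 99 splits, 94 gave no call, and the 5 with calls all exchanged 1 RNA array with 1 DNA array. Among the 13 drawn splits that parted all 5 site pairs 1, the real one, gave as many and the highest other gave 8092; only 16 such splits exist, too few for a share under 0.05. The real split also follows the slides, so it says nothing of molecule against slide.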

How the results depend on the processing

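Tests limited to the run or to the other probes, normexp correction of the median signal, scaling by E1A spots, the slide term for the fourth comparison and the fits without sites 2 and 5 were chosen after the data were seen. Normexp on the mean signal was not run, since the scanner files used here hold the median signal, and the gene list tests and their alternatives were not run. DNA against the control soil and the fourth comparison gave 0 calls under all 19 and all 20 alternatives. For RNA against the control soil, calls rose from 0 to 71 without a filter on dim probes, 31 with normexp, 11 with probes of a target averaged and 4 with all 12 arrays in 1 fit, and leaving out a site gave 0 to 1 (1 without site 5). The main count was 0, as in 13 of 18 alternatives. Without the filter the fitted differences of the 4 named probes were unchanged. The fit then held 15140 probes, of which 11371 were not above background on any RNA array, and these entered the variance that limma shares between probes. The calls added there did not come from larger differences of these probes. For the other alternatives the cause was not tested. For RNA against DNA, 9962 became 2437 with median scaling, 2444 in the authors' value table, 1459 with quantile normalization and 2274 with the 75th percentile of all probes. Fewer probes were tested with detection on at least 50% of the arrays (1380 calls), with probes of a target averaged (798) and in the run alone (371). Leaving out a site gave 9223 to 9859. With site as a replicate block the count was 9991, and the block changed no other call. The site match stayed on the same side of the threshold throughout, while its mean turned to −0.0024 with Spearman rho and to −0.032 outside the run. Leaving out a site gave 0.012 to 0.040. The detected-probe difference kept its direction, from −3206 to −5367 without a site. The gap between run and other probes kept its direction in all 8 alternatives, from 6.68 to 11.11 log2 units. Of the named probes, G_BA_105324 reversed to −0.27 with probes of its target averaged, and G_BA_102943 in the fourth comparison, well above background on 2 of 12 arrays, went from 3.63 to −0.05 with normexp. On the DNA arrays of sites 2 and 5 and on the RNA arrays outside the run, few spots rose above background, which limits what can be compared there.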

Other observations

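The counts in this part, except the single-site values of AJ404680, were chosen after the data were seen, and none is a test. The 2 sets of probes for the 110 targets of the run agreed closely within an array, with a correlation across targets of 0.969 or higher on all 12 arrays.

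Target AJ404680 of the run gave the probe with the largest RNA difference above the control soil at sites 1, 3 and 4, by the planned rule for single sites. These probes were not well above background in the control RNA, so the differences are at least 365-fold at site 1, 51.4-fold at site 3 and 873-fold at site 4. All 8 of its probes were detected in the RNA of sites 1, 3, 4 and 5, none at site 2 and 1 in the control soil. In DNA, 8 were detected at site 4, 7 at site 2, 6 at site 1 and 0 at sites 3 and 5 and in the control soil. It was 1 of the 11 targets past the threshold with probes averaged, and none of its probes passed when tested singly with the dim-probe filter and scaling used in the report. Without a filter on dim probes, all 11 targets had a probe that passed. That fit used the same arrays and shared its variance with 11371 probes not above background on any RNA array. It is therefore no separate support for these targets.

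Outside the run, target NT03BP0141 was 1 of the 6 targets detected on every RNA array, at a mean log2 signal of 5.88 ± 1.34 at the contaminated sites (SD, n = 5) and 6.05 in the control soil. It was singled out after its values were seen. The bright corner spots, also controls, had a median log2 signal of 4.91 and 8.03 on the DNA arrays of sites 2 and 5, which share slide 2, and between 10.501 and 12.394 on the DNA arrays of slide 1.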
